A study of Homo sapiens with 48 samples.

How the data were processed

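RNA of K562 cells was measured on Affymetrix arrays in 48 samples. K562 is an established human leukaemia cell line that carries the BCR-ABL1 fusion kinase, and imatinib is an inhibitor of that kinase. Per the labels, the samples carry 8 letters, A to H, and each letter holds 3 mock-treated samples and 3 samples treated with 1 micromolar imatinib for 24 hours. The labels do not say what a letter marks, so the letters are called sets here. Targets were made from about 8 micrograms of total RNA in both treatments, per the labels. The keywords of the imatinib samples also name mock treatment, while their description and title give imatinib; the description and title were used.

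Per the labels, RNA of the mock samples was isolated with Trizol followed by a column kit, and RNA of the imatinib samples with the column kit alone. The labels also give the mock samples the full standard amount of RNA spike controls and the imatinib samples a reduced one, which corresponds to a planned log2 ratio of -1. Both differences run along with the treatment in every set, so treatment and isolation method could not be told apart.

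The authors deposited 1 value per probe set and sample on the log2 scale, for 22283 probe sets. The background correction, the summary over probes and the normalization between arrays are not given in the sources used here. That the scale is log2 was read from the values, which lie between 2.41 and 14.9, since a 16-bit scanner cannot give so high a value on a natural or base-10 log scale. The mean over probe sets differed by at most 0.053 between samples of the same set and lay between 5.89 and 7.60 over the sets. Levels were therefore compared within sets, and no level of a set was compared with that of another set. No signal-to-background values were used here, and for arrays the number of samples limits the precision.

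All columns were already on a log scale and were used as deposited. The 68 control probe sets were kept out of the tests, which left 22215. Probe sets were named through the platform annotation, with symbols updated by gene number from the RefSeq gene table of assembly GRCh38.p14. Of the tested probe sets 19065 had 1 gene symbol, 1043 had several and 2107 had none; 19053 of those with 1 symbol matched the gene table. A gene was represented by its probe set with the highest mean, among those with 1 symbol, which gave 11963 genes.

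Whether the sets were 8 versions of the same samples was checked first. Samples with the same number in different sets deviated from their group means with a median correlation of 0.020 over 168 pairs, against -0.012 over 336 pairs with different numbers. By the rule fixed before the data were examined, all 48 samples therefore entered the fit as separate samples, with the set as a factor. The check compared samples by their number only, so it cannot tell whether the samples of a treatment share a source of RNA. No pair of replicates held identical values: in the closest pair the largest difference of a probe set was 0.67 log2. Nothing in the labels says that samples came from separate cultures, so p-values measure the spread between these samples, which may be technical.

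Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), and adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. The combined fit compared 24 imatinib with 24 mock samples. Each set was also fitted alone, 3 samples against 3, and a fit with set-by-treatment terms tested whether the change differed between sets. Errors of log2 changes are standard errors of the combined fit unless stated otherwise. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 27 lists, with camera at an estimated correlation and fry beside it. The lists were written before the data were examined and hold 531 entries, of which 458 were measured. Control probe sets were compared by exact permutation of the 6 samples of a set, and over the 8 sets by an exact sign-flip permutation test, both two-sided. Figures were drawn with matplotlib 3.10.9.

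The named genes followed a rule fixed before the data were examined. It took the 12 largest rises and the 12 largest falls among genes past the threshold with the same sign in every set and a mean level at or above the median of all probe sets. It also took up to 4 members of each list with the smallest p at such a level, BCR and ABL1, the spike controls, and the actin and GAPDH control probe sets. This named 121 genes. Genes named outside this rule are marked as such where they appear.

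The fits were tested on simulated data. In the simulated combined comparison of 22215 probe sets, 49 of 50 changes of 0.25 log2 were recovered, and all 50 at 0.5, 1 and 2 log2, with 14 false calls among 213. In the simulated comparison of set F, 0 of 50 changes of 0.25 log2, 15 of 50 at 0.5, 40 of 50 at 1 and 49 of 50 at 2 were recovered. With the mitosis list shifted by 0.5 log2 in a simulation of 11963 genes, camera called it in 20 of 20 runs, and called 2 of 520 tests of other lists. Simulated errors were independent between genes, whereas the correlation estimated for the mitosis list in the data was 0.318. These runs therefore do not show how often camera miscalls lists of correlated genes.

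The alternatives tried were quantile normalization within sets, centring of arrays, leaving out the dimmer probe sets, leaving out each set or each replicate, averaging over sets by mean or median, the replicate number as a block, other variance priors, and other choices of probe set per gene. Alternatives chosen after seeing the data are marked in the closing section.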

Results

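Gene expression was measured in K562 cells, a human leukaemia line driven by the BCR-ABL1 kinase, after 24 hours in 1 micromolar imatinib or mock treatment. Imatinib blocks that kinase. The data hold 48 samples in 8 sets, A to H, with 3 mock and 3 imatinib samples in each set. The comparison asked which transcripts differed between treated and mock samples, and it could be computed in each of the 8 sets. The labels do not say whether sets or samples came from separately treated cultures. Agreement between sets may therefore be technical and is not a count of repeated treatments. Values are log2 levels of 22215 probe sets, and the median replicate SD of a probe set lay between 0.061 and 0.147 over the 16 groups. RNA isolation differed between the treatments in every set, as described under the processing.

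Imatinib-treated cells had higher levels of genes of red cell formation and lower levels of genes of growth signalling, protein and ribosome production, and cell division. Values of a gene are those of its brightest probe set. Among the genes named below, CDKN1C, ASAH1, HSPA4, DCN, PAX5, RPS10 and YWHAZ each had a dimmer probe set that did not pass. In the combined fit of 24 against 24 samples, 14478 of 22215 probe sets, or 65.2%, passed an adjusted p of 0.05 in limma. Of these, 8740 were higher and 5738 were lower after imatinib. With 1 probe set per gene, 4978 of 11963 genes were higher and 3237 lower. The counts of list members below are to be read against that background. Most of the changes were small: 331 probe sets were at least 2-fold higher and 476 were at least 2-fold lower. Of the 14478 changed probe sets, 8630, or 59.6%, had the same sign in all 8 sets, and so had all 807 of those changed at least 2-fold, whose selection by size favours an equal sign. The balance of small changes depended on scaling. With arrays centred on their median, 6194 were higher and 6638 lower. Leaving out the dimmer probe sets lowered the count to 9019, since fewer were tested.

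The largest rise was that of ALAS2, the first enzyme of heme synthesis in red cell precursors, whose level went from 6.57 to 11.49, a log2 change of 4.91 ± 0.06 (SE, n = 24 per treatment) or 30.1-fold. The water channel gene AQP1 rose by 4.14 ± 0.08 and the transcriptional cofactor LBH by 4.13 ± 0.06. COL18A1, a collagen gene, rose by 3.87 and SLC4A1, which encodes the red cell anion exchanger band 3, by 3.67. PPOX, an enzyme of heme synthesis, rose by 3.49, and SLC25A37, the mitochondrial iron importer mitoferrin, by 3.39. RELN rose by 3.24, HBZ, the embryonic zeta globin, by 3.13, TSC22D1 by 3.10, the zinc transporter family member SLC30A10 by 2.89 and ADD2, a membrane skeleton protein, by 2.80. Adjusted p-values of these 12 genes ranged from 2.03e-49 for PPOX to 1.05e-28 for SLC25A37 in limma. Each was called higher in all 8 sets when the sets were fitted alone.

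The largest fall was that of SLC2A3, a glucose transporter, which dropped by 3.84 ± 0.07 log2, so that mock cells had 14.3-fold the level of imatinib cells. HHEX, a homeobox transcription factor of blood progenitors, fell by 3.68 ± 0.06. TMEM158 fell by 3.47 and EGR1, an early response transcription factor, fell by 3.42. IGFBP4 fell by 2.95, PDE4DIP fell by 2.94 and the chemokine gene CXCL8 fell by 2.82. ID1 fell by 2.81, the Fc receptor gene FCGR2A fell by 2.73, SAMSN1 fell by 2.63, MLLT11 fell by 2.59 and SERPINB9, a granzyme inhibitor, fell by 2.54. Adjusted p-values of these 12 genes ranged from 2.02e-44 for PDE4DIP to 1.07e-28 for SAMSN1 in limma. All were called lower in each of the 8 sets. Other probe sets of the same genes moved in the same direction, but by different amounts: a further EGR1 probe set fell by 1.31, and the other probe sets of ADD2 rose by 0.46 and 0.87.

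**Figure D1:**
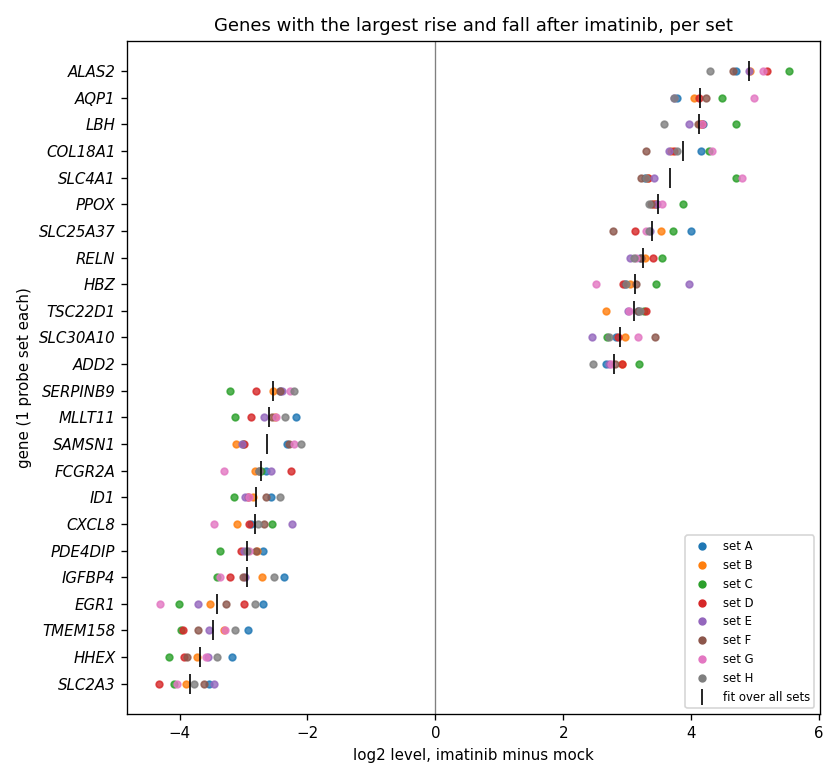
Log2 level in imatinib minus mock samples (x axis) for the 12 genes with the largest rise and the 12 with the largest fall (y axis). Each point is 1 of the 8 sets, the mean of 3 samples minus the mean of 3, and the black tick is the combined fit. The genes were selected to have the same sign in every set; their points run from 5.53 for ALAS2 in set C to -4.33 for SLC2A3 in set D.

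Genes of red cell identity rose as groups. Of 21 measured genes of the erythroid membrane and its regulators, 20 rose and 0 fell, with a median log2 change of 1.55 (camera adjusted p = 1.44e-14). XK and TAL1 each rose by 2.44, KLF1, a transcription factor of red cell genes, by 2.22 and the blood group gene ICAM4 by 2.15. Of 10 genes of heme synthesis and mitochondrial iron, 9 rose and 1 fell, with a median of 1.44 (camera adjusted p = 2.85e-08). FECH, which inserts iron into protoporphyrin to form heme, rose by 2.50 and UROS by 1.25. All 5 measured globin genes rose, with a median of 1.15 (camera adjusted p = 1.53e-06). Beside HBZ, HBD rose by 2.05, HBQ1 by 1.15 and HBE1, already at 12.66 in mock cells, by 1.04. Globin genes are similar in sequence, so their probe sets can share signal. The other probe set of HBE1 rose by 0.22 only, and the dimmer probe sets of TAL1 rose by 1.22 and 0.14. Medians of the erythroid list lay between 1.15 and 1.97 in the 8 sets.

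Genes of the platelet lineage showed mostly small changes. Of 15 measured megakaryocyte genes, 9 rose and 3 fell, with a median of 0.11. Only 7 of the 15 were at or above the median level of all probe sets, so a change of the others could be missed. The list did not stand apart from other genes by camera (adjusted p = 0.326). It passed by fry (adjusted p = 5.63e-06), which tests against no change and not against other genes. TUBB1, a beta tubulin of platelets, rose by 2.39, from a level of 5.77. GP9 rose by 0.19, GP1BA by 0.12 and PF4 by 0.11, and the calls of GP1BA and PF4 were lost under some alternative settings.

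Targets and feedback genes of the pathways downstream of BCR-ABL1 were lower. Of 14 STAT5 target genes, 9 fell and 2 rose, with a median of -1.0 (camera adjusted p = 1.85e-05). Beside ID1, the signalling inhibitor SOCS2 fell by 2.15 and MYC fell by 1.36, while the cyclin gene CCND3 rose by 1.10 ± 0.03. Of 16 genes of ERK feedback and early response, 12 fell and 2 rose, with a median of -0.76 (camera adjusted p = 3.74e-06). ETV5 fell by 1.90, SPRED2, an inhibitor of the ERK pathway, fell by 1.36 and IER3 fell by 1.12. The dimmer ETV5 probe sets fell by 0.72 and 0.60, and of those of SPRED2 the brighter fell by 0.33 while the dimmer, with a change of 0.05, did not pass (limma adjusted p = 0.159). After either other scaling 0 ERK genes rose. Among 9 measured imatinib target kinases and BCR, 4 rose and 1 fell (camera adjusted p = 0.779). That list had a median of 0.07 and a mean of -0.09. The kinase LYN fell by 1.75, KIT rose by 0.21, ABL1 rose by 0.32 ± 0.03 and BCR rose by 0.14 ± 0.04. Fusion and normal transcripts of BCR and ABL1 were not told apart by these probe sets.

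Genes that supply protein and ribosome production were lower. All 18 measured genes of ribosome biogenesis and the nucleolus fell, with a median of -0.72 (camera adjusted p = 3.87e-13). DDX21 fell by 1.63, NOP16 fell by 1.59, NOLC1 fell by 1.44 and MRTO4 fell by 1.19. NOP16 was the 1 named gene whose probe sets disagreed past the threshold: of its other 3, 1 fell by 1.28, while the remaining ones, at levels of 5.68 and 6.25, each rose by 0.10. Of 23 genes of ATF4 and the amino acid response, 21 fell and 0 rose, with a median of -1.08 (camera adjusted p = 1.24e-14). The tryptophan tRNA synthetase gene WARS1 fell by 1.95, TRIB3 fell by 1.73, asparagine synthetase ASNS fell by 1.71 and DDIT4 fell by 1.61. Of 13 genes of endoplasmic reticulum chaperones and the unfolded protein response, 12 fell, with a median of -0.72 (camera adjusted p = 1.24e-07), among them HSP90B1, which fell by 1.74, HSPA5, which fell by 1.64, SDF2L1, which fell by 1.24, and XBP1, a transcription factor of that response and not a chaperone, which fell by 1.12. Of 10 heat shock genes 9 fell, with a median of -0.44 (camera adjusted p = 4.4e-05); HSPE1 fell by 0.83, HSPA4 fell by 0.75, HSP90AA1 fell by 0.53 and HSP90AB1 fell by 0.41. After quantile normalization 7 fell. Of 17 genes of nucleotide and polyamine synthesis, 14 fell and 2 rose, with a median of -0.66 (camera adjusted p = 2.07e-08). SRM fell by 1.68, PFAS fell by 1.34, GART fell by 0.88 and ODC1 fell by 0.71.

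The transcripts of the ribosomal proteins themselves went both ways. Of 35 measured, 13 rose and 8 fell with a median of 0.02 (camera adjusted p = 0.824). With centred arrays 5 rose and 10 fell, with a median of -0.02, and after quantile normalization 9 rose and 11 fell. RPS9 rose by 0.24, RPS27 by 0.20 and RPS28 by 0.13, and RPS10 fell by 0.13.

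Mitosis genes were lower, while genes of DNA replication were mixed. Of 27 mitosis genes 25 fell and 1 rose, with a median of -0.56 (camera adjusted p = 6.19e-13). CDC20 fell by 1.33, the kinase PLK1 fell by 1.11, cyclin B1 (CCNB1) fell by 1.06 and TPX2 fell by 0.79. Of 32 genes of DNA replication and the G1/S transition, 10 rose and 16 fell, against 13 and 11 after quantile normalization within sets, and the list did not pass by camera (median -0.09, adjusted p = 0.199). CDT1 rose by 0.61 and CCNE1 by 0.38, whereas RFC3 fell by 0.56 and CDC45 fell by 0.45. Of 20 CDK inhibitors and genes linked to FOXO and quiescence, 14 rose and 2 fell, with a median of 0.26 (camera adjusted p = 0.000899). CITED2 rose by 2.66, the CDK inhibitor gene CDKN1C by 1.58, YPEL5 by 1.54 and FOXO3 by 1.13.

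Genes of glucose use and sterol synthesis were lower. Of 19 genes of glycolysis and glucose uptake, 14 fell and 2 rose, with a median of -0.42 (camera adjusted p = 1.53e-06). After quantile normalization 14 fell and 5 rose. Beside SLC2A3, the pyruvate kinase gene PKM fell by 2.33, HK2 fell by 1.76 and ENO1 fell by 0.98. Dimmer probe sets fell by 0.34 for PKM, by 0.27 for HK2 and by 0.25 for ENO1. Of 17 genes of cholesterol synthesis and uptake, 11 fell and 3 rose, with a median of -0.56 (camera adjusted p = 9.75e-05). IDI1 fell by 1.2, DHCR7 fell by 1.04, INSIG1 fell by 0.87 and FDPS fell by 0.65. Genes of oxidative phosphorylation went both ways: 11 of 27 rose and 11 fell, with a median of -0.02 (camera adjusted p = 0.35, fry adjusted p = 0.00975). After quantile normalization 13 rose and 6 fell, with a median of 0.06, and with centred arrays 5 rose and 13 fell, with a median of -0.06. Cytochrome c (CYCS) fell by 1.31, NDUFS1 fell by 0.63, and COX8A and ATP5F1B each fell by 0.28. Of 21 genes of lysosome and autophagy, 13 rose and 5 fell, with a median of 0.33 (camera adjusted p = 0.00105). This call was lost with an adjusted p = 0.123 with an estimated correlation. The acid ceramidase gene ASAH1 rose by 2.28, the protease gene CTSB by 1.51, NPC2 by 1.12 and PSAP by 0.95.

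Genes of the BCL2 family, which holds promoters and inhibitors of apoptosis, went both ways. Of 16 measured, 7 rose and 5 fell; the median was 0.07, the mean -0.22 and the camera direction downward (adjusted p = 0.541). The 4 named members all fell: PMAIP1 fell by 1.98 and BID by 1.26, both promoters of apoptosis, and MCL1 fell by 1.48 and BCL2L1 by 0.80, both inhibitors.

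None of the 4 lists of other cell types' markers stood apart from other genes by camera. At or above the median level of all probe sets were 4 of 10 T cell and 3 of 8 B cell markers. For monocyte and granulocyte markers it was 0 of 11, and for fibroblast and epithelial markers 7 of 12. A change of the dimmer members could be missed. Of 10 T cell markers 4 rose and 1 fell (median 0.09, mean -0.08, camera adjusted p = 0.793). CD3D fell by 1.73, from a level of 8.12, whereas CD5 rose by 0.22 and CD3E by 0.17, and CD8A had a log2 change of 0.09 that did not pass (limma adjusted p = 0.10). Of 8 B cell markers 6 rose, with a median of 0.10 (camera adjusted p = 0.326, fry adjusted p = 5.58e-05). Their changes were small: CD22 rose by 0.19 and CD79A by 0.12, and PAX5 had a change of 0.08 with a call that many settings lost. With centred arrays 2 of the 8 rose, and after quantile normalization 3. Of 11 monocyte and granulocyte markers 4 rose and 1 fell (median 0.06, camera adjusted p = 0.787), against 1 and 1 under either other scaling. Of 12 fibroblast and epithelial markers 4 rose and 3 fell (median 0.03, -0.01 with centred arrays, mean -0.18, camera adjusted p = 0.456, fry adjusted p = 4.87e-16). With centred arrays 2 rose and 3 fell, and after quantile normalization 3 and 3. The keratin genes KRT8 and KRT18 fell by 1.44 and fell by 1.11, and COL1A1 rose by 0.18 and DCN by 0.19. Of 23 interferon response genes 17 rose and 1 fell, against 12 and 1 with centred arrays, and the list did not pass by camera (median 0.11, adjusted p = 0.059, fry adjusted p = 6.56e-09). BST2 fell by 0.87, while IRF9 rose by 0.51, IRF1 by 0.39 and IFI35 by 0.22. Of 9 housekeeping genes 2 rose and 4 fell, with a median of -0.06 (camera adjusted p = 0.166, fry adjusted p = 6.22e-09). With centred arrays 2 rose and 6 fell, and after quantile normalization 4 and 4. The actin gene ACTB fell by 0.36, YWHAZ fell by 0.35, TBP fell by 0.30 and PPIA fell by 0.17.

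**Figure D2:**
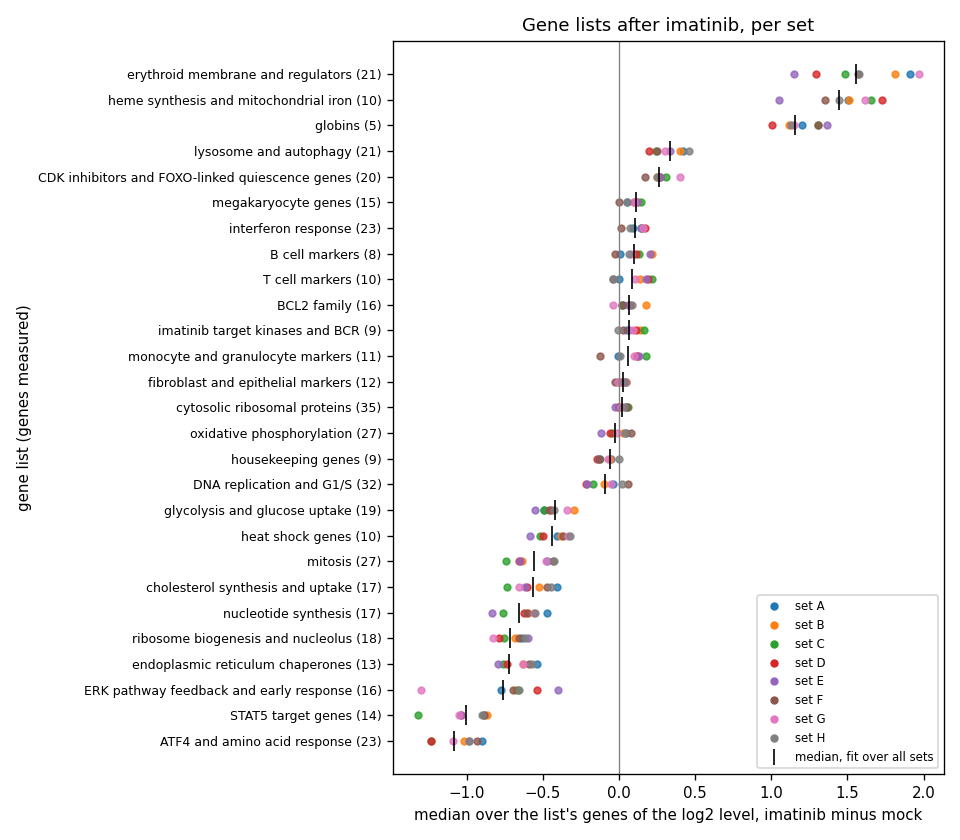
Median over the genes of each of the 27 lists of the log2 level in imatinib minus mock samples (x axis), with the number of genes measured in brackets (y axis). Each point is 1 of the 8 sets and the black tick the median in the combined fit; the erythroid list lies between 1.15 and 1.97 and the ATF4 list between -1.23 and -0.90.

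By camera, 15 of the 27 lists passed, 5 upward and 10 downward, and 14 passed with an estimated correlation. The heat shock list was nearest the threshold there (adjusted p = 0.0478 with an estimated correlation). By fry, which asks whether the genes of a list move on balance in the same direction, all lists passed except ribosomal proteins and imatinib target kinases (adjusted p = 0.0866 for each), monocyte markers (0.16) and T cell markers (0.954). Fry tests against no change, and 65.2% of all probe sets were called, so a pass by fry does not set a list apart. The BCL2 list passed by fry (adjusted p = 1.45e-17) with 7 genes up and 5 down. With p-values adjusted over the list alone, 3 ERK genes, 11 megakaryocyte genes and 1 gene of the chaperone list rose, and 6 lysosome genes and 12 oxidative phosphorylation genes fell. The other counts adjusted over the list alone were the same as those over all probe sets.

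The 8 sets gave similar changes. Across probe sets, which are not independent replicates, the log2 changes of pairs of sets correlated with a Pearson r between 0.815 and 0.952, with a median of 0.903 over 28 pairs. Fitted alone, the sets called 6282 probe sets in A, 10598 in B, 8654 in C, 8646 in D, 4307 in E, 3660 in F, 6105 in G and 5343 in H. At least 5 sets called 2072 probe sets upward and 2978 downward, and all 8 sets called 875 upward and 1459 downward. Only 67 probe sets were called upward in a set and downward in another, 31 of them above the median level. The count of set C fell to 5324 without mock replicate 2 and to 5450 without mock replicate 3, and that of set E rose to 7371 without imatinib replicate 1. The size of the change differed between sets for 1599 probe sets, by a test of the set-by-treatment terms.

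On average the spike controls were lower after imatinib, by less than the planned log2 ratio of -1. Averaged over 24 poly-A control probe sets, the difference was -0.29 ± 0.14 (SD, n = 8 sets), below 0 in 8 of 8 sets (exact sign-flip permutation p = 0.00781, the smallest possible with 8 sets, adjusted 0.0172). Over sets, the dap control had a mean of -0.56, thr -0.27, phe -0.19 and lys -0.14. The labels do not say which controls were reduced. Within sets the dap difference ran from -0.89 in D to -0.18 in F, and no set alone can give an exact permutation p under 0.1. Single dap probe sets did reach the planned ratio in some sets. A 3-prime one ran from -1.14 in B to -0.01 in C, and a middle one from -1.20 in D to -0.26 in C. The hybridisation controls, added after labelling, differed by -0.09 ± 0.29 (SD, n = 8 sets, exact sign-flip permutation p = 0.398), and by -0.16 without imatinib replicate 2 and -0.06 without imatinib replicate 3. With the hybridisation difference of each set subtracted, the poly-A difference ran from -0.86 in A to 0.22 in E, and was 0.07 in H. The fall of the poly-A controls in 8 of 8 sets therefore does not by itself show a reduced spike amount. For the trp control the mean was 0.02, above 0 in 6 of 8 sets (exact sign-flip permutation p = 0.0312, adjusted 0.0491). Control probe sets for 18S ribosomal RNA differed by -0.35 ± 0.74 (SD, n = 8 sets, exact sign-flip permutation p = 0.266), with -1.72 in set G and -1.17 in set A, where mock samples were at 10.03. For 28S the mean was 0.32, above 0 in 7 of 8 sets (exact sign-flip permutation p = 0.0312, adjusted 0.0491).

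RNA integrity was read from the 3-prime and 5-prime control probe sets of GAPDH and actin. The log2 ratio of GAPDH 3-prime over 5-prime differed between treatments by 0.02 ± 0.08 (SD, n = 8 sets, exact sign-flip permutation p = 0.531). That of actin differed by 0.15 ± 0.19 (SD, n = 8 sets, exact sign-flip permutation p = 0.0469, adjusted 0.0645), up to 0.44 in set F. The GAPDH control probe sets had log2 changes of -0.16 at the 3-prime end, -0.20 in the middle and -0.18 at the 5-prime end, and the actin ones -0.29, -0.43 and -0.45.

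**Figure D3:**
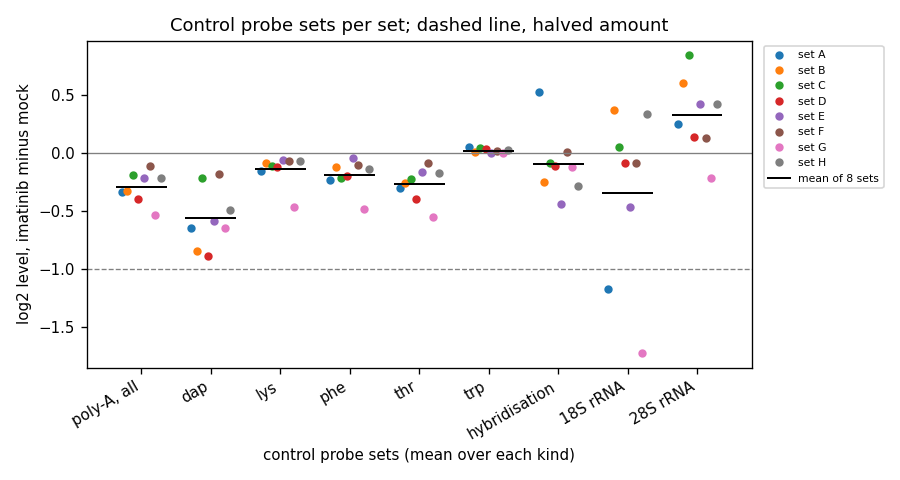
Log2 level in imatinib minus mock samples (y axis) of each kind of control probe set (x axis). Each point is 1 of the 8 sets, the black line their mean, and the dashed line the planned ratio of -1; the dap points lie between -0.89 and -0.18, and the 18S points spread from -1.72 to 0.37.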

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

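The tests of RNA degradation, of low control signal and of unequal hybridisation were chosen only after the values they bear on had been seen.

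The size of the imatinib change differed between sets for 1599 probe sets by the set-by-treatment terms in limma, with set G showing the largest change in 615 of them and set C in 566. A scale factor of each set may account for part of it but not for all. After dividing the values of each set by its overall slope, 913 probe sets still differed, 869 of them among the first ones. Compression of dim signals that differs between sets may contribute. The SD over sets of the fold-change slope was 1.92 times as large in the 202 dimmest of the probe sets changed at least 2-fold as in the 202 brightest, with a bootstrap interval at 95% of 1.62 to 2.22 that spans the bound of 2 set beforehand, so this stays open. What a letter marks is not stated, so no biological explanation was tested.

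The rise of red cell genes, and the combined count of 14478 that it is part of, was set against chance, RNA degradation and RNA isolation. Of 100 splits of the samples within sets, 1 gave as many changed probe sets, the real split itself. This argues against a chance division of these samples as the source of the combined count. The splits counted all probe sets and did not score the red cell genes by themselves. The highest other splits gave 5943 and 5833, and the remaining 97 gave under 100. The first of these had 36 of 48 samples grouped as in the real treatment and the second 28, while some splits with 32 gave 0; why they called so many was not tested. RNA degradation is argued against in 2 sets only and stays open for the others. In the 7 sets whose GAPDH 3-prime over 5-prime ratio moved by under 0.1, the lowest median of the erythroid list was 1.29, but all 8 sets, from 1.15 to 1.97, lay over the bound of 0.786, so no choice of sets could have failed. A second form, tried after that was known, took the 2 sets in which the actin ratio also moved by under 0.1, B at 1.81 and D at 1.29. As a test against that bound it is open to the same objection. The GAPDH and actin ratios moved by -0.015 and -0.072 in B, and by -0.053 and -0.019 in D. The erythroid list thus rose there without a rise of either ratio. That argues against degradation, as read from these 2 transcripts, as the cause in sets B and D. RNA isolation cannot be told apart from treatment, since 0 samples had the method of the other treatment. The rise may therefore be a response to imatinib, as a hypothesis, with the isolation method left open, and RNA degradation too outside sets B and D.

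On average the poly-A controls stood nearer to 0 than the planned -1. Control probe sets above the median level had a mean of -0.46 ± 0.07 (SE over sets). If all poly-A controls were halved, this argues against low signal as the whole cause. Which were halved is not stated, and only 3 (set H) to 14 (set C) of the 24 probe sets were that bright, so low signal stays open. Unequal hybridisation is argued against under the same condition, since the poly-A difference minus that of the hybridisation controls was -0.20 ± 0.12 (SE over sets), and -0.10 without set A. Those controls are added after labelling, so they do not bear on RNA load or labelling. These, which controls were reduced, and the authors' processing may matter and stay open. No biological explanation was tested.

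Splits of the 6 samples of a set are too few for a share under 0.05, as there are 10 per set. In each set the real split gave the most, 1 of the 10, with 6282 changed probe sets in A, 10598 in B, 8654 in C, 8646 in D, 4307 in E, 3660 in F, 6105 in G and 5343 in H, and the highest other split gave 0.

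The change differed in size between sets in 2 of the 6 probe sets for 18S ribosomal RNA, 1 of the 6 for 28S and 5 of the 24 poly-A ones. It also differed in 38 of the named genes, which kept their direction in every set. For the following values, each is the adjusted p of the set-by-treatment terms in limma. TUBB1 had 1.47e-10, with a log2 change from 1.10 in set E to 4.01 in set G. Among the other rising genes, HBZ had 7.74e-06, ALAS2 1.44e-05, SLC4A1 3.71e-05, AQP1 0.000116, HBE1 0.000314, LBH 0.0104, ADD2 0.0194, FECH 0.0196, COL18A1 0.0312 and HBD 0.0466. SLC4A1 rose by 4.71 in set C and 4.8 in set G, and by 3.22 to 3.42 in the others. Among falling genes of signalling and transcription, ETV5 had 1.57e-06, IGFBP4 4.21e-05, TMEM158 0.000199, HHEX 0.000701, CXCL8 0.00134, IER3 0.00653, EGR1 0.00831, FCGR2A 0.00847, MLLT11 0.00864, SOCS2 0.0118, SPRED2 0.0206, LYN 0.0236, PDE4DIP 0.0311 and SAMSN1 0.0432. Among falling genes of growth and metabolism, PLK1 had 0.00472, DDIT4 0.00886, DDX21 0.00914, TRIB3 0.0123, HSPA5 0.0262, WARS1 0.0287, XBP1 0.0361, ASNS 0.0395, CYCS 0.0396, INSIG1 0.0443 and PKM 0.0494. CD3D had 0.00316 and KRT8 0.0033.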

How the results depend on the processing

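The fits with the 8 sets as replicates and with 16 group means, and the median over sets with values scaled first, were chosen only after the data were seen. Of 221 counts and control values under the alternatives, 213 stayed within the bounds, which for a count is 1.5 times the value reported, for a control value 1 SD over sets and for the agreement between sets the SD over pairs of sets, and no called gene or list and no control value reversed, while centring arrays turned the balance of the combined count to 6194 higher and 6638 lower, and scaling turned the sign of some list medians near 0. The combined count of 14478 fell to 9019, with 4535 higher, when the dimmer probe sets were left out, which tests fewer. Averaging 6 samples by the median over sets, as planned, gave 9974 changed, within the bound, and 5342 higher. That planned form was first run with arrays centred beforehand, which gave 9337 changed and 4009 higher; another form, chosen after those counts were seen, centred probe sets by set and gave 13523 and 8011. The cause was not tested. Centring arrays alone gave 12832. Leaving out each replicate gave 12191 to 14214, leaving out each set 13072 to 15000, the 8 sets as replicates 12248 and 16 group means 14763. For set C leaving out each replicate gave 5324 to 9681, and for set E 2995 to 7371. Settings of the floor for linear values did not apply and were not run, as all columns were log values. Same-numbered mock and imatinib samples of a set did not deviate together (median r 0.016, from -0.52 to 0.49), and the replicate block gave 14063. All 15 lists that passed kept their call by camera at the preset correlation under the settings run for lists, which leave out the variance priors; with an estimated correlation 14 passed. Of 701 list values 7 became significant: interferon without set H (0.0446), without mock replicate 1 (0.0424), without imatinib replicate 1 (0.048), with the replicate block (0.0482) and with sets as replicates (0.0385), within a range of 0.0385 to 0.189; and BCL2 (0.0253) and housekeeping (0.0325) with all probe sets. Of 3172 gene values 39 lost and 1 gained a call: PAX5 lost it in 18 settings, CD79A in 4, CD3E and PF4 in 3 each, DCN, GP1BA and RPS28 in 2 each, BCR, CD5, COL1A1, KIT and RPS10 in 1 each, and CD8A gained it in 1.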

Other observations

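The genes in this part were chosen after their values were seen, except CXCL8 and TUBB1. Beside CXCL8, a pair of other chemokine genes picked for their values fell. CXCL3 fell by 2.04 ± 0.09 (SE, n = 24 per treatment), from a level of 6.79, and CXCL2 fell by 1.55 ± 0.09, from 6.25. Both were called lower in all 8 sets. Their sizes varied between sets, from -3.10 to -1.24 for CXCL3 and from -2.63 to -0.80 for CXCL2. The dimmer CXCL8 probe set fell by 1.78.

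NQO2, which encodes an oxidoreductase known to bind imatinib, fell by 2.45 ± 0.05, so that mock cells had 5.48-fold the level of imatinib cells (limma adjusted p = 1.03e-39). Its change lay between -2.81 and -2.15 in the 8 sets. TUBB1 was the member of the megakaryocyte list that moved most among those named, rising in 8 of 8 sets while that list did not pass by camera.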
